A study of Homo sapiens with 6 samples.

How the data were processed

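RNA sequencing of 6 libraries from PC3 cells, a human prostate cancer cell line, was analysed. Per the labels' protocols, the cells were stained with an antibody against NRP2 and separated by flow cytometry into a population with high and a population with low NRP2, then kept in culture for up to 2 weeks, and RNA was taken at different passages. RNA was isolated with a column kit for small inputs, and a service company built the libraries and sequenced them. The library kit and whether it keeps strand are not given in the sources used here, nor is the aligner. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart.

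The authors deposited 1 table of TPM values (a length-scaled share of transcripts: read counts divided by gene length and scaled so that each library has the same total) for 27958 genes with their lengths and positions. Per the submitters' processing notes, featureCounts 1.5.2 and DESeq2 1.20.0 were among the tools and hg38 (GRCh38.p12) was the genome build; the notes used here give neither their roles nor their order. All 27958 gene identifiers and start positions match GENCODE release 29, and 21558 also match in their end position. Of the genes in the table, 15279 are protein coding, and none is at 0 in every library. TPM is a share, so a gene group that takes more of 1 library lowers every other value in it.

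A library was tied to its group by the group word in its column name. The names carry S numbers that appear in no label, so libraries are called here by these numbers (S38, S39 and S40 for NRP2-high, S35, S36 and S37 for NRP2-low), and the replicate numbers of the labels could not be attached to them. Nothing in the labels says that the libraries of a group come from separate sorts or cultures, so p-values measure only the spread between these samples, which may be technical.

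TPM multiplied by gene length, divided by its smallest non-zero value in the library, gave whole numbers for 100% of the non-zero values of every library at a tolerance of 0.001. The read totals obtained in this way are the depth, between 17551302 and 30726744 reads per library. Called genes that rest on few reads are counted in the results. Within each group the libraries differed by far more than sampling noise, with a chi-square per gene between 21.6 and 110.7 over the pairs, so all were kept as separate samples.

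The main test was fixed before the data were examined. Genes with a TPM of at least 1 in at least 3 of the 6 libraries were kept, which left 15214 genes, 11068 of them protein coding. Values were log2(TPM + 1), with a pseudocount of 1. The difference NRP2-high minus NRP2-low was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with group as the only term and Benjamini-Hochberg adjustment over all genes kept. Log2 fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. Some are given with their standard error (SE) or a 95% confidence interval, and the others without. The threshold was an adjusted p of 0.05. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

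Genes were named by a rule fixed before the data were examined. A set of genes was always named, among them NRP2, CD274, NRP1, VEGFA and VEGFC. Of the genes past the threshold with groups that do not overlap and a mean TPM of at least 5 in the higher group, the 12 with the largest and the 12 with the smallest log2 fold change were named, leaving out unnamed loci. From each fixed list up to 4 called members, or otherwise up to 2 members with the highest mean TPM, could be named. Genes named outside this rule are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

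There were 26 fixed gene lists with 664 entries, of which 605 matched a gene of the table. The 22 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists. The count of members past the threshold was taken over all genes and also adjusted over the list alone. An estimated correlation, ranks, and fry, a rotation test that asks whether the genes of a list move on balance one way, were alternatives.

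The test was tried on simulated data, reads drawn for the real genes from the real libraries' means, depths and spread, with 15154 genes tested. The genes to be changed were drawn only from those with a mean TPM of at least 5. The rates that follow therefore do not cover genes under that level, CD274 among them. The test called 3 of 67 genes changed 1.5-fold (4.48%), 17 of 67 changed 2-fold (25.4%) and 58 of 66 changed 4-fold (87.9%), all in the right direction. It also called 10 genes that had not been changed, 11.4% of its calls. With no gene changed it called 0 of 15285. A list raised 1.5-fold was called, and with nothing changed 0 of the 22 lists were called. The spread was drawn for each gene separately, so the simulated genes were not correlated. The list result therefore does not show how camera behaves on lists whose genes vary together.

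The alternatives were a pseudocount of 0.1, no filter, a mean TPM of at least 5, rescaling by the median log ratio, quantile normalization, leaving out mitochondrially encoded genes, no variance trend, array weights, and leaving out each library in turn. Added after seeing the data were limma's voom on the recovered reads, the mitochondrial share as a covariate, and the VEGF receptor list without NRP2. The deposited unit is TPM, so tests made for counts were not the main result. The planned fit with the replicate number as a block was not run, since the columns carry no such number.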

Results

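Transcript levels were compared between PC3 cells sorted for high and for low NRP2. PC3 is an androgen-independent line from a bone metastasis of human prostate cancer, and NRP2 (neuropilin-2) is a cell surface co-receptor for vascular endothelial growth factors and class 3 semaphorins. Each group had 3 libraries. NRP2-high libraries S38, S39 and S40 held 22397000, 21673710 and 23130636 reads, and NRP2-low libraries S35, S36 and S37 held 30726744, 23137706 and 17551302 reads. Library S37 stood apart: mitochondrially encoded genes took 31.0% of its TPM, against 14.3% in S35, 15.1% in S36 and 11.1% to 18.7% in the NRP2-high libraries. Pearson correlations of log2(TPM + 1) lay between 0.959 and 0.978 within NRP2-high, between 0.965 and 0.983 within NRP2-low, and between 0.937 and 0.970 across the groups. The first principal component held 43.7% of the variance and did not separate the groups: S37 was at 56.8 and S40 at 10.5, S38 at -40.8, S39 at -28.5, S35 at -2.34 and S36 at 4.38.

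The gene used for sorting was compared first. NRP2 (ENSG00000118257.16, GRCh38, chromosome 2, 205681990 to 205798133, plus strand) was at 35.7 ± 16.8 TPM (SD, n = 3) in NRP2-high and 5.12 ± 2.42 TPM (SD, n = 3) in NRP2-low libraries. The libraries were at 48.1, 42.5 and 16.6 TPM (S38, S39, S40) against 7.55, 5.10 and 2.71 TPM (S35, S36, S37), so the groups did not overlap. The log2 fold change was 2.53 (SE 0.43, limma adjusted p = 0.0375). The call ended when S38 (adjusted p = 0.126), S39 (0.160), S36 (0.153) or S37 (0.154) was left out, with a log2 fold change of 2.21 to 2.57 in these fits, and stayed without S40 or S35. The call also ended with a pseudocount of 0.1, without a filter and without a variance trend.

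The title of the series concerns PD-L1, the ligand of the T cell checkpoint receptor PD-1, which CD274 encodes. CD274 (ENSG00000120217.13, chromosome 9, 5450503 to 5470566, plus strand) was at 8.28, 2.48 and 1.47 TPM in NRP2-high libraries S38, S39 and S40 and at 3.64, 0.792 and 0.786 TPM in NRP2-low libraries S35, S36 and S37. The means were 4.08 ± 3.68 and 1.74 ± 1.65 TPM (SD, n = 3 each). The log2 fold change was 0.81 (SE 0.55, 95% interval -0.44 to 2.05, limma adjusted p = 0.874). In this unpaired fit it did not exceed the spread between libraries, and the interval leaves room for a change of more than 2-fold upward. Taken in column order, S38 lay above S35, S39 above S36 and S40 above S37. The labels do not say that these are pairs, and a paired difference was not tested. With a library left out the log2 fold change ran from 0.25 without S38 to 1.21 without S40 and 1.27 without S35. With array weights, which did not converge, it was -0.13. PDCD1LG2, which encodes the second PD-1 ligand, was below the filter, with 0.489 ± 0.549 TPM in NRP2-high and 0.856 ± 0.533 TPM in NRP2-low libraries (SD, n = 3 each).

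**Figure D1:**
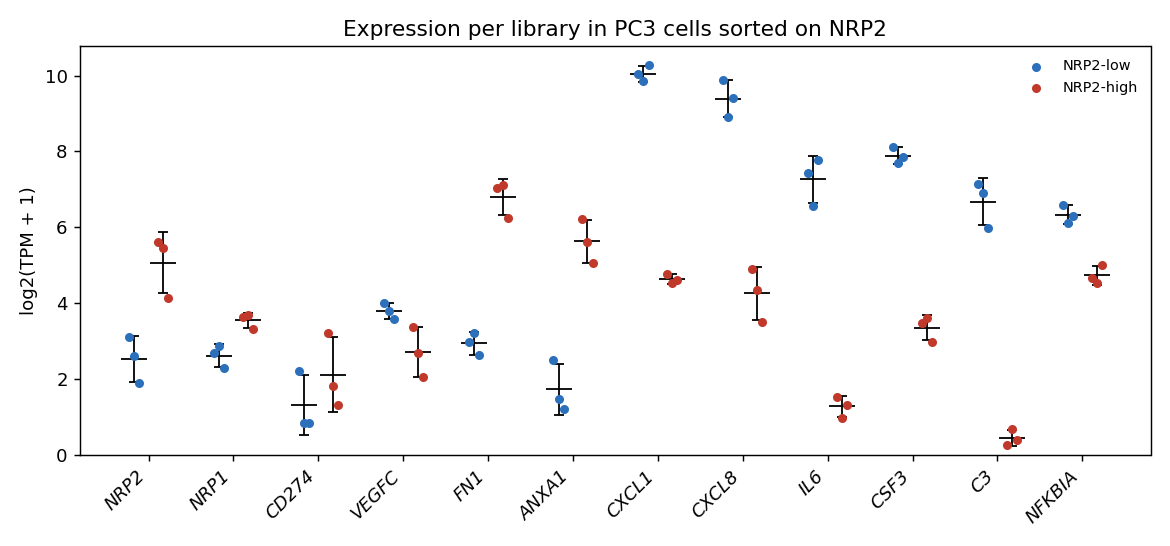
Level of 12 genes in each library, as log2(TPM + 1) on the vertical axis, with a blue point per NRP2-low and a red point per NRP2-high library, and the mean with its SD in black (n = 3 per group). NRP2, FN1 and ANXA1 lie higher in NRP2-high, CXCL1, CXCL8, IL6, CSF3, C3 and NFKBIA lie lower, and the CD274 points of the groups overlap.

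Among 15214 genes tested, 53 rose and 74 fell in NRP2-high cells relative to NRP2-low cells, 127 in all, and 126 of these changed at least 2-fold on the log2(TPM + 1) scale. Of the 127 genes, 98 are protein coding. The groups did not overlap for any of the 127, whereas 11.97% of all tested genes had groups that did not overlap, against 10% by chance. At an unadjusted p under 0.05 there were 1065 genes. Of the called genes, 10 are shorter than 200 bases and rest on 3 to 15 reads over the 6 libraries. In all, 14 called genes had under 50 reads over the 6 libraries, and 17 had a group at 0. The count was 43 without S36, 54 without S39, 69 without S38, 73 without S35, 88 without S37 and 97 without S40. In all 6 of these fits 38 of the 127 genes stayed past the threshold, 13 higher and 25 lower. A stable call can still rest on few reads: the 13 include RNU6-548P, named after its values were seen, with 9 reads in NRP2-high and 0 in NRP2-low libraries. The median log2 fold change of all tested genes was 0.10 as deposited, and 0.00 after scaling by the median log ratio, so values near 0 are read relative to that shift.

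Of the 12 genes with the largest rise, FN1 had the highest level. FN1, fibronectin, was at 113 ± 33.8 TPM in NRP2-high and 6.76 ± 1.56 TPM in NRP2-low libraries (SD, n = 3 each; log2 fold change 3.85, SE 0.27, adjusted p = 0.000299). IGFBP4, a binding protein of insulin-like growth factors, was at 39.9 ± 9.23 against 1.44 ± 0.617 TPM, with a log2 fold change of 4.07. ANXA1, a phospholipid-binding protein with anti-inflammatory roles, was at 51.0 ± 20.5 against 2.56 ± 1.80 TPM, with a log2 fold change of 3.91. ZBED2, a zinc finger transcription factor, rose by 4.31 on the log2 scale, NELL2 by 3.28, the planar polarity gene PRICKLE1 by 2.73, the lysosomal protease gene CTSZ by 2.45 and the neurotrophin gene BDNF by 2.36. Each of these genes stayed past the threshold with any library left out. ABI3BP (2.39) and the transporter gene SLCO2B1 (2.31) were also among the 12, as was NRP2, and both lost the call in 5 of the 6 fits, with adjusted p up to 0.173 for ABI3BP without 1 of S38, S39, S40, S36 or S37 and up to 0.179 for SLCO2B1 without 1 of S39, S40, S35, S36 or S37.

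**Figure D2:**
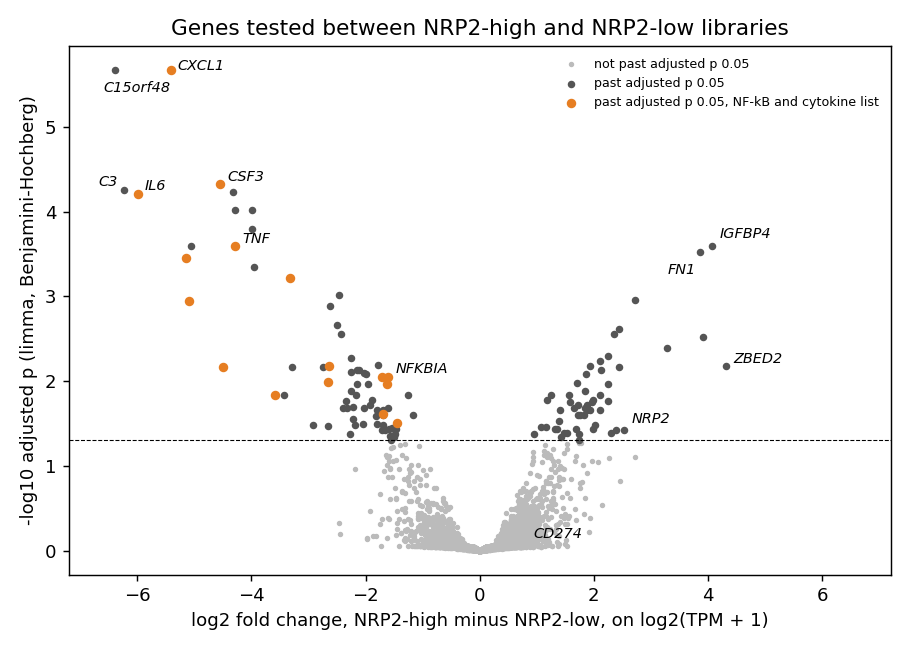
Each point is a tested gene, with the log2 fold change NRP2-high minus NRP2-low on the horizontal axis and -log10 of the limma adjusted p on the vertical axis. The dashed line marks an adjusted p of 0.05, orange points are called members of the NF-kB and cytokine list, and all 16 of these lie on the negative side, while CD274 lies below the line.

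The 12 genes with the largest fall included cytokine genes. CXCL1, a neutrophil-attracting chemokine (chromosome 4, 73869393 to 73871242), was at 23.9 ± 2.14 TPM in NRP2-high and 1070 ± 158 TPM in NRP2-low libraries (SD, n = 3 each; log2 fold change -5.42, SE 0.17, adjusted p = 2.15e-06). CXCL8, interleukin-8, was at 19.6 ± 9.33 against 698 ± 232 TPM (log2 fold change -5.14). IL6 was at 1.44 ± 0.447 against 162 ± 63.7 TPM (-5.99), and CSF3, the granulocyte colony-stimulating factor gene, was at 9.31 ± 2.22 against 238 ± 36.8 TPM (-4.55). C15orf48 (-6.40) and complement C3 (-6.24) fell further still. IL1B had 0 reads in every NRP2-high library and 37.9 ± 21.3 TPM in NRP2-low libraries, at least 668-fold lower against a floor of 3 reads over the group. IL13RA2 (-5.06), the EGF receptor ligand gene TGFA (-4.32), DNER (-4.30), TNF (-4.28) and CXCL2 (-4.49) were the others of the 12. All but CXCL2 stayed past the threshold with any library left out, and CXCL2 lost the call without S37 (adjusted p = 0.0551). CXCL1, CXCL2, CXCL3 and CXCL6 are related copies in 1 cluster, so how reads were divided between them is uncertain.

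The fixed list of NF-kB targets and inflammatory cytokines was the list with the most changed members: 16 of its 25 tested members fell and 0 rose, with a median log2 fold change of -1.69 (-1.80 to -1.57 with a library left out). Adjusted over the list alone, 18 fell and 1 rose, LIF, which encodes an interleukin-6 family cytokine and had a log2 fold change of 0.47. LIF and the members in the next sentence were named after their values were seen. Besides the cytokines above, those that fell were NFKBIA (-1.60), which encodes the inhibitor of NF-kB, the apoptosis inhibitor BIRC3 (-1.71), the adhesion molecule ICAM1 (-2.66), the superoxide dismutase SOD2 (-1.62), TNFAIP2 (-1.69), CCL20 (-2.64), CSF2 (-3.59), CXCL3 (-1.46) and CXCL6 (-3.32). In camera the list's adjusted p was 3.72e-53, with an estimated correlation the adjusted p = 0.0795, and in fry the adjusted p was 0.00468. When no filter was applied 10 of 31 tested members fell and 0 rose. Without each library in turn 11 to 14 members fell, 11 without S39 or S36 and 12 without S37, and 8 members (CXCL1, CXCL8, IL6, IL1B, TNF, CSF3, CCL20, CXCL6) were called in all 6 fits. Those called members that lost the call were CXCL3 and TNFAIP2 in every fit, SOD2 without S39 or S36, CSF2 without S39 or S37, BIRC3 and ICAM1 without S36, NFKBIA without S39 and CXCL2 without S37. Library S37, with its mitochondrial share of 31.0%, is among the NRP2-low libraries compared here.

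Camera with its preset correlation called 11 of the 22 lists, 4 upward and 7 downward, but it also called 4 to 11 lists in each of the splits of the 6 libraries that mixed the groups. These splits keep part of the difference between the groups, so they are not comparisons without one. With an estimated correlation camera called 0 lists (at an unadjusted p under 0.05 the NF-kB list, p = 0.00361), and fry called 1, the NF-kB list. In the mixed splits fry called 1 list, not the NF-kB list, for S38, S39 and S37 against the rest, and 0 in the others. The lists below are therefore described by their members.

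In the list of VEGF receptors, neuropilins and ligands 1 of 12 tested members rose, NRP2. Adjusted over the list alone 4 rose, NRP2, NRP1, SEMA3C and PLXND1, and 1 fell, VEGFC (members named after their values were seen, except NRP2, NRP1 and VEGFC). NRP1 was at 10.7 ± 1.56 against 5.19 ± 1.23 TPM (SD, n = 3 each; log2 fold change 0.93, adjusted p = 0.185) and VEGFC at 5.98 ± 3.15 against 12.96 ± 1.96 TPM (-1.09, adjusted p = 0.363). The log2 fold changes were 0.60 for SEMA3C, 0.80 for PLXND1 and -0.02 for VEGFA (8.55 ± 1.65 against 8.91 ± 3.01 TPM). The list's median was 0.48 (0.37 to 0.58 with a library left out) and its camera adjusted p was 0.0151, and with an estimated correlation the adjusted p = 0.833. NRP2, on which the cells were sorted, is part of this list, and without it the camera adjusted p was 0.0756.

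None of the 10 tested immune checkpoint ligands and related surface proteins passed the threshold by limma, adjusted over all genes or over the list alone, and 9 lay above 0 (median 0.24, or 0.14 after scaling by the median log ratio; camera adjusted p = 0.141). The median was 0.20 to 0.35 with a library left out, except without S37, where it was 0.099 and 7 of the 10 lay above 0, and without S35 the camera adjusted p was 0.0493. CD276 (B7-H3) was at 27.3 ± 4.36 against 24.5 ± 7.87 TPM, CMTM6, a stabiliser of PD-L1 protein, at 232 ± 29.1 against 192 ± 23.3 TPM, and NT5E (CD73) at 167 ± 84.5 against 184 ± 42.9 TPM (SD, n = 3 each). None of the 24 interferon response genes passed either (median 0.25, camera adjusted p = 0.312). Their median was 0.18 to 0.35 with a library left out, except 0.074 without S37, where 14 of the 24 lay above 0. IRF1 had a log2 fold change of -0.31 (adjusted p = 0.883). Of the 18 genes of MHC class I antigen presentation 0 passed, with a median of -0.06, or -0.15 after scaling by the median log ratio. The median was -0.22 without S37 (16 of 18 below 0) and turned above 0 without S35 (0.038) or S36 (0.020). Their camera adjusted p was 0.00564 (0.150 without S40), and with an estimated correlation the adjusted p = 0.833. B2M was at 132 ± 20.9 against 189 ± 40.6 TPM, with S37 at 235 TPM.

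Among mesenchymal genes 1 of 17 rose, FN1, and adjusted over the list alone 5 rose: FN1, CDH2, SNAI2, THBS1 and FSTL1, all but FN1 named after their values were seen. CDH2, N-cadherin, was at 82.9 ± 17.97 against 34.5 ± 9.09 TPM (SD, n = 3 each; log2 fold change 1.25, adjusted p = 0.0816, and 0.0387 after scaling by the median log ratio). THBS1 was at 187 ± 181 against 35.0 ± 7.68 TPM, with S40 at 393 TPM, and log2 fold changes were 0.91 for SNAI2 and 0.82 for FSTL1. VIM, vimentin, was at 1096 ± 300 against 800 ± 312 TPM (0.51, adjusted p = 0.874). The list's median was 0.51, 0.19 without S37 and 0.74 without S40. Its camera adjusted p was 0.00132, and with an estimated correlation the adjusted p = 0.833. Of 16 epithelial junction and keratin genes 2 fell, the desmosome gene DSP (5.25 ± 2.45 against 39.3 ± 17.8 TPM, -2.66) and the tricellular junction gene MARVELD2 (-1.69), and each kept the call in 1 of the 6 fits without a library, DSP in that without S37 and MARVELD2 in that without S40. The highest adjusted p in these fits was 0.161 for DSP and 0.164 for MARVELD2. The median of this list was 0.21 and its mean -0.05 (camera adjusted p = 0.664, downward), so these differ in sign. CDH1, E-cadherin, had 1 read in NRP2-high and 3 reads in NRP2-low libraries.

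All 23 tested cholesterol biosynthesis genes lay above 0, with a median log2 fold change of 0.46 (0.35 after scaling by the median log ratio, 0.41 to 0.56 with a library left out). None passed the threshold over all genes, and 10 passed adjusted over the list alone. FDPS was at 432 ± 33.9 against 322 ± 44.9 TPM (SD, n = 3 each). The list's camera adjusted p was 1.57e-10, with an estimated correlation the adjusted p = 0.714, and in fry the adjusted p was 0.202.

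In the other lists 0 members passed the threshold over all genes. Medians of the log2 fold change were 0.29 for 15 stem and progenitor genes (camera adjusted p = 0.162), 0.31 for 7 Hedgehog genes (0.646), 0.16 for 24 YAP and TAZ targets (0.363), 0.07 for 34 proliferation genes (0.592), 0.07 for 27 hypoxia and glycolysis genes (0.467), 0.04 for 25 endoplasmic reticulum stress genes (0.324), 0.24 for 10 androgen receptor and luminal genes (0.927) and 0.03 for 17 immediate early genes (0.646). The medians of the proliferation, hypoxia, stress and immediate early lists turned below 0 after scaling by the median log ratio, and without S37 those of the stem (-0.04), luminal (-0.24), epithelial (-0.01), proliferation (-0.12, 22 of 34 below 0), hypoxia, stress (-0.23) and immediate early (-0.23) lists did so. Without S37 the Hedgehog median was 0.063 and that of YAP and TAZ targets 0.052. With any of the other libraries left out the medians ran from 0.13 to 0.56 for the stem, 0.18 to 0.45 for the Hedgehog, 0.12 to 0.40 for the YAP and TAZ, 0.018 to 0.17 for the proliferation, 0.072 to 0.22 for the hypoxia, 0.10 to 0.37 for the luminal and 0.12 to 0.31 for the epithelial list. Some of these lists were called with a library left out. The stem list was at a median of 0.56 without S35 (camera adjusted p = 0.0118) and 0.55 without S40 (0.0131), and YAP and TAZ targets were at 0.40 without S35 (0.0177) and 0.36 without S39 (0.0187). The hypoxia list was at -0.21 without S37, with 26 of 27 genes below 0 (0.000137). The stress list was at 0.37 without S35 (0.0493), -0.18 without S38 (0.00732) and -0.098 without S36 (0.0308), and the immediate early list at 0.47 without S35 (0.00551) and -0.19 without S38 (0.0132). The immediate early median was also below 0 without S36 (-0.048). GLI1, a Hedgehog transcription factor, was below the filter at 1.63 ± 1.15 against 0.531 ± 0.313 TPM, and MYC was at 163 ± 26.4 against 169 ± 57.2 TPM (SD, n = 3 each). Camera called the 24 integrin, laminin and focal adhesion genes upward (median 0.27, adjusted p = 0.0445), 28 MYC targets downward (-0.07, 0.00491), 15 heat shock and metallothionein genes downward (median 0.02, mean -0.14, 0.0258), 56 ribosomal protein genes downward (-0.02, 0.0234) and 22 histone genes downward (-0.09, 0.0234). With an estimated correlation their adjusted p = 0.917, 0.884, 0.833, 0.917 and 0.833, in the same order. The call of the integrin list ended without S37 (median 0.026, 14 of 24 above 0, adjusted p = 0.590), S38 (0.443) or S39 (0.135), without a filter (0.0541), at a mean TPM of at least 5 (0.206), without a variance trend (0.0677), with array weights (0.305), on ranks (0.0552) and with the mitochondrial share as a covariate (0.728). The medians with a library left out ran from 0.026 to 0.50 for the integrin list, -0.22 to -0.0051 for MYC targets and -0.16 to -0.052 for histone genes. The median of the heat shock list ran from -0.16 without S40 to 0.19 without S38. That of ribosomal protein genes was -0.098 without S36, and turned to 0.028 without S37 (35 of 56 above 0) and 0.042 without S40 (37 of 56 above 0). The call of MYC targets ended without S38 (0.153) or S39 (0.135). That of heat shock genes ended without S38 (0.282) or S36 (0.0859), with median log ratio scaling (0.0591), quantile normalization (0.0987), array weights (0.270), voom (0.0555) and the mitochondrial covariate (0.0613), and on ranks (0.212). That of ribosomal protein genes ended without S39 (0.118), S40 (0.466) or S37 (0.472), without a filter (0.0869), with array weights (0.0523) and with the covariate (0.530). That of histone genes ended without S38 (0.443) or S37 (0.542), with median log ratio scaling (0.0809), quantile normalization (0.0731), array weights (0.904), voom (0.158) and the covariate (0.530).

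All 15 mitochondrially encoded genes lay below 0 in NRP2-high libraries, with a median log2 fold change of -0.35, and 0 passed the threshold. The camera adjusted p was 0.000359, and with an estimated correlation the adjusted p = 0.833. Without S37 the median was -0.0068 and 7 of the 15 genes lay above 0, and without S38, which had the lowest mitochondrial share, the median was -0.13 and the call ended (adjusted p = 0.0530). The median was -0.57 to -0.39 with any of the other libraries left out. The call also ended without S37 (0.627), with quantile normalization (0.172) and with array weights (0.904), which did not converge. With the mitochondrial covariate the adjusted p was 0.966. That covariate is the summed share of mitochondrially encoded genes, so this outcome follows from its construction and says nothing further. Of the marker lists for leukocytes, fibroblasts and smooth muscle, and endothelium, 1 gene each was above the filter: CORO1A (4.987 against 3.995 TPM), RGS5 (1.72 against 0.998 TPM) and ESAM (4.97 against 8.36 TPM), NRP2-high first, none of them past the threshold. Of the neuroendocrine list 3 genes were tested and 0 passed (median 0.14).

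**Figure D3:**
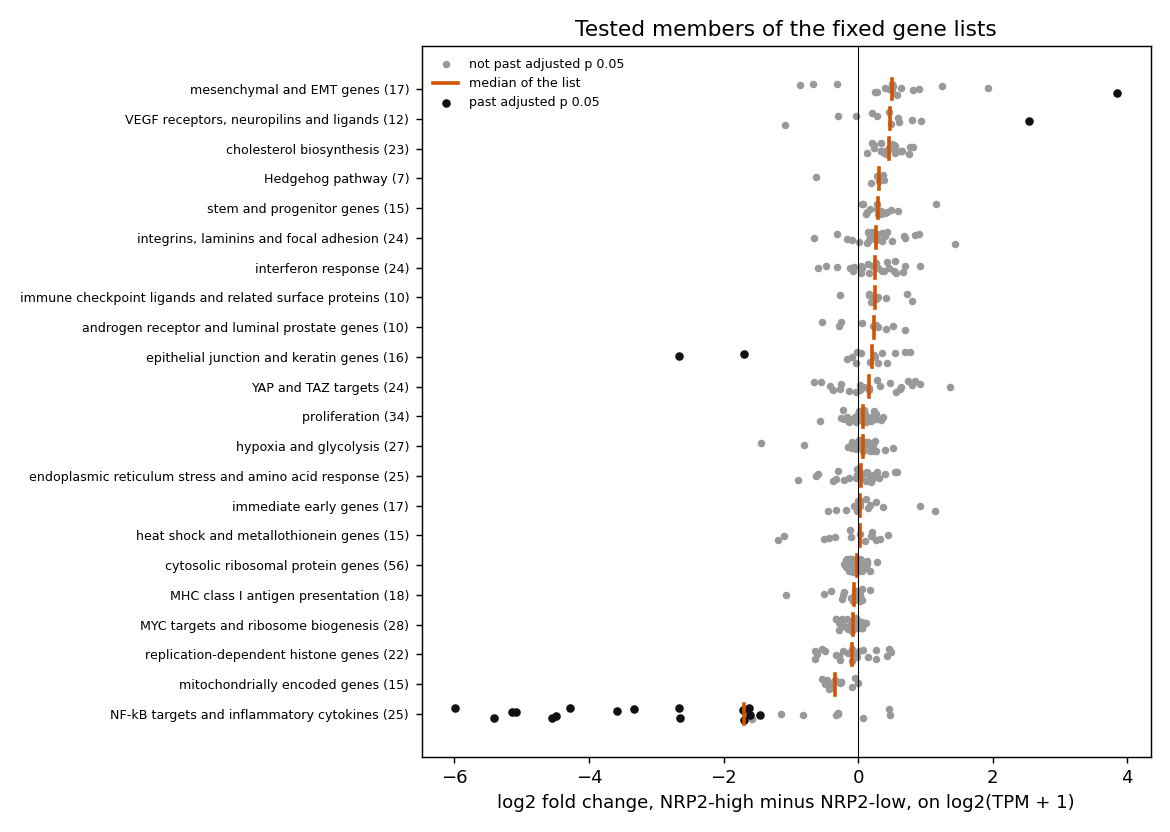
Log2 fold changes NRP2-high minus NRP2-low of the tested members of fixed lists, with the number tested in brackets. Black points passed an adjusted p of 0.05, grey points did not, and an orange bar marks each list's median. Only the 22 lists with at least 5 tested genes are drawn, with a median of -1.69 for the NF-kB list and between -0.35 and 0.51 for the others.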

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

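The settings with voom, with the mitochondrial share as a covariate and with the VEGF list without NRP2 were chosen after seeing the data. No paired analysis was possible because the columns of the table carry no replicate number, so the planned fit with a block was not run. A pairing by column order was not tried. In that order, deviations within the groups had Pearson correlations of 0.444 (S38 with S35), 0.079 (S39 with S36) and 0.423 (S40 with S37). The other pairs across the groups lay between -0.449 (S40 with S35) and 0.075 (S39 with S35). Libraries may thus share variation by column order, which the unpaired fits count as spread. None of the 127 called genes changed direction in any setting. Causes were not tested except where the setting's construction gives them. Without a filter, with 27958 genes tested, 74 genes passed (29 higher, 45 lower, 61 at least 2-fold) and 55 of the 127 kept their call. With a mean TPM of at least 5 54 passed (18 higher, 36 lower, all 54 at least 2-fold), the 54 that kept their call of 58 called genes tested. Array weights gave 3960 (2259 higher, 1701 lower, 687 at least 2-fold): the weights did not converge, and S35 (7.50) and S39 (5.27) outweighed the rest. Voom on recovered reads gave 197 (84 higher, 113 lower), with 113 of the 127 among them. With a library left out the counts ran from 43 to 97, the higher ones from 15 to 44, the lower ones from 28 to 59, and those at least 2-fold from 43 to 97. A pseudocount of 0.1 gave 93, no variance trend 154, the scalings 153 and 154, no mitochondrial genes 156 and the mitochondrial covariate 163. Depth and spread limit what could be called: in simulated data 17 of 67 genes changed 2-fold were called. These were drawn from genes with a mean TPM of at least 5, and lower genes were not tried.

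NRP2 kept its direction throughout. Its log2 fold change was 2.75 with a pseudocount of 0.1 (adjusted p = 0.0565), 2.53 without a filter (0.175) and 2.53 without a variance trend (0.0502), so no longer called, and 2.21 to 2.998 with a library left out. CD274 passed in no setting, was at 0.25 to 1.27 with a library left out, and at -0.13 with array weights (adjusted p = 0.791, and 0.475 or more in every setting). Of the 943 values of the other 60 named genes 813 kept direction and side of the threshold, 102 lost the call, 20 gained it and 8 changed sign. Those that changed sign had passed in no main test. CD276 was at -0.055 with the mitochondrial covariate and at -0.093 to 0.37 with a library left out. With a library left out VEGFA was at -0.25 to 0.20, MYC at -0.23 to 0.24 and NT5E at -0.60 to 0.24.

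List tests are given by adjusted p. With an estimated correlation the calls ended for the VEGF, MHC class I and mesenchymal lists (0.833 each), cholesterol (0.714) and NF-kB (0.0795), and with fry for the VEGF (0.543), MHC class I (0.834), mesenchymal (0.527) and cholesterol (0.202) lists. The VEGF call ended at a mean TPM of at least 5 (0.0554), with array weights (0.0910) and without NRP2 (0.0756), and the mesenchymal call with array weights (0.104). Lists without a call gained it in some settings: the interferon list at a mean TPM of at least 5 (0.0424), the stem list without S35 (0.0118) or S40 (0.0131), YAP and TAZ targets without S35 (0.0177) or S39 (0.0187), the checkpoint list without S35 (0.0493), and the hypoxia list without S37 (0.000137) and with the mitochondrial covariate (0.00662). So did the stress list without S35 (0.0493), S38 (0.00732) or S36 (0.0308), with array weights (3.01e-05) and with the covariate (0.0167), and the immediate early list without S35 (0.00551) or S38 (0.0132) and with array weights (3.05e-05). With a library left out the checkpoint list ranged from 0.0493 to 0.457 and MHC class I from 0.000107 to 0.150. Direction turned for the epithelial list without a filter (0.810), on ranks (0.568) and with a library left out (0.367 to 0.851), for YAP and TAZ targets (0.0785), mitochondrial (0.904) and histone genes (0.904) with array weights, and for immediate early genes without a filter (0.831). For the luminal list it turned without a filter (0.686), at a mean TPM of at least 5 (0.828), with the scalings (0.892 and 0.935), without mitochondrial genes (0.923), on ranks (0.841), and with a library left out (0.185 to 0.755). In fry, which does not compare a list with other genes, the proliferation, hypoxia, stress, luminal and immediate early lists turned (0.977 each). With a library left out direction turned in at least 1 fit for the Hedgehog (0.381 to 0.995), proliferation (0.0727 to 0.776), hypoxia (0.000137 to 0.663), stress (0.00732 to 0.975), immediate early (0.00551 to 0.836), ribosomal protein (2.02e-06 to 0.472) and mitochondrial (1.03e-07 to 0.627) lists. Genes with a mean TPM under 5, CD274 among them, and the Hedgehog list have no value under the stricter filter, and the mitochondrial list has none without its genes.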

Other observations

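Both tests of leukocyte RNA and the test of library S37 for the mitochondrial genes were chosen only after the result was seen, and the genes of the next paragraph were picked after their values were seen. The second leukocyte test was added after the first had left the explanation open.

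Among called genes outside the fixed lists, 5 with roles in innate immune signalling were picked out; no list of such genes was tested. The receptor gene TLR2 was at 0.228 ± 0.0964 TPM in NRP2-high and 5.16 ± 2.69 TPM in NRP2-low libraries, the adaptor MYD88 at 0.361 ± 0.113 against 3.12 ± 0.150 TPM, the kinase IRAK2 at 9.985 ± 1.16 against 53.9 ± 26.0 TPM, the inflammasome sensor NLRP3 at 0.558 ± 0.397 against 4.64 ± 0.407 TPM and IL18R1 at 0.221 ± 0.133 against 2.96 ± 0.519 TPM (SD, n = 3 each). Their log2 fold changes were -2.23, -1.60, -2.21, -1.88 and -1.69 (limma adjusted p = 0.0283, 0.0207, 0.0200, 0.0168 and 0.0221). Most of these calls ended with 1 library left out: TLR2 kept the call only without S37, MYD88 without S40, IRAK2 without S35 or S37, NLRP3 without S38, and IL18R1 in none of the 6 fits, with adjusted p up to 0.154 for TLR2, 0.136 for MYD88, 0.102 for IRAK2, 0.106 for NLRP3 and 0.142 for IL18R1. Upward, the vitamin D hydroxylase gene CYP24A1 was at 151 ± 19.4 against 39.5 ± 10.7 TPM (log2 fold change 1.94), IGFBP7 at 264 ± 44.4 against 80.8 ± 20.8 TPM (1.71), WNT7A at 5.32 ± 0.571 against 0.466 ± 0.283 TPM (2.12) and the WNT inhibitor DKK1 at 36.5 ± 3.31 against 15.997 ± 3.12 TPM (1.16). CYP24A1 and WNT7A kept the call in all 6 fits, IGFBP7 lost it without S39 (adjusted p = 0.0597) and DKK1 in every fit (up to 0.196).

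The fall of NF-kB and cytokine genes was weighed against 3 technical explanations. With the mitochondrial share as a covariate the median log2 fold change of the 16 called members was -3.29, against -3.46 without it, and all 16 stayed past the threshold. These members were picked by their calls in the same libraries, so this fit is a weak test. TPM is a share, so the higher mean mitochondrial share of NRP2-low libraries would lower these genes there, not raise them. That direction argues against the share as the whole cause. Without S37 12 of the 16 stayed, and the median log2 fold change of the 16 was -3.24. Both values argue against that library as the sole source. RNA from leukocytes was tested first by the highest NRP2-low mean among the listed abundant leukocyte genes, that of CORO1A. It was at 3.995 ± 1.65 TPM (SD, n = 3) against a bound of 5 TPM, and within its spread this test left the explanation open. The bound looks at NRP2-low libraries alone. In NRP2-high libraries the mean of CORO1A was higher, at 4.987 ± 2.17 TPM (SD, n = 3), which is not the direction of the explanation, though within the spread. The median over these genes in NRP2-low libraries, a test added afterwards, was 0.459 TPM. PTPRC had 3 reads in NRP2-low libraries and LYZ had 0. These low values argue against leukocyte RNA for these genes together. LAPTM5 went the other way, at 0.902 ± 0.553 TPM (61 reads) in NRP2-low against 0.124 ± 0.0217 TPM in NRP2-high libraries (SD, n = 3 each), below the bound but leaving a small part open. Other explanations stay open and were not all listed. Among them are a difference in culture or passage between the groups, which the labels do not tie to libraries, and a difference that comes with NRP2 itself. Neither of these was tested. Gained or lost chromosome segments, treated below, stay open as well.

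The lower level of mitochondrially encoded genes in NRP2-high libraries may come largely from library S37. The other NRP2-low libraries had a mean mitochondrial share of 14.7%, inside the NRP2-high range of 11.1% to 18.7%. Without S37 the difference was nearly gone and the camera call ended, as given above. Its size also depended on S38, which had the lowest share at 11.1%. Without S38, and with S37 kept, the median log2 fold change of these genes moved from -0.35 to -0.13 (camera adjusted p = 0.0530). That fit does not show a difference apart from S37. No biological explanation of the high share in S37 was tested.

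Neighbouring genes shifted together: the SD of the median log2 fold change over 218 windows of 10 Mb was 0.0688, above the 95th percentile of 0.0467 with gene positions shuffled, and 0 of 1000 shuffles reached it. Gained or lost chromosome segments between the sorted populations are a candidate explanation, but a split that mixed the groups (S38, S39 and S35 against the rest) gave 0.0951. Relative to the median of its own shuffles the real split was at 1.61 and this one at 1.53, and a different mixed split (S38, S35 and S37) was at 1.68. Such segments and other sources of regional differences between libraries cannot be told apart here. By limma 0 windows passed the threshold, and 0 had an unadjusted p under 0.05. The windows were fitted without rescaling, and S37 lay low across them, with a median log ratio of -0.267 over the tested genes. This widened the spread within NRP2-low, so these counts say little on whether segments differ.

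The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 127 genes and the highest of the others 1, so that 1 of the 10 splits, the real one, gave as many. For genes changed at least 2-fold the numbers were 126 and 1. For lists called by camera they were 11 and 11, with 3 of the 10 splits giving as many. For the NF-kB list, fry's p was 0.000213 in the real split and at least 0.289 in the others. Camera's adjusted p for this list was 3.72e-53 in the real split and under 0.05 in 8 of the 9 other splits, down to 7.48e-10. The mixed splits keep part of the group difference, since their sides hold unequal numbers of NRP2-high libraries. How many of these calls come from that part cannot be told.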
